A study of Oryza sativa with 4 samples.

How the data were processed

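RNA of callus from seeds of the OsGLK1-FOX line (FOX denotes overexpression of a full-length cDNA) and of a vector control line was hybridised in pairs to 4 arrays, with the vector control in Cy3 and OsGLK1-FOX in Cy5 on each. Per the labels, 400 ng of RNA was labelled and 1 µg of each labelled cRNA used, and the design text states 4 biological replicates. The labels differ on the culture. The growth description gives 13 days in constant white light and 30 mg/l of the auxin 2,4-D, whereas the design text gives 14 days at 30 °C and 30 mg/l of hygromycin. Replicate numbers were taken from the source names, since 2 samples share a title.

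Spot and background intensity values were deposited as the scanner software gave them, per the file headers by Feature Extraction 9.5.3.1. The authors' processed intensity values had been detrended and dye-normalised by LOWESS with a smoothing factor of 0.25, per the file headers. The deposited log ratios are log10 of Cy5 over Cy3 processed signals, per the file headers. The series value table differed from these log10 values by less than 0.005 on each array, with a column median of 0, so it is a rounded copy and no independent source; its direction, scale and centring follow from that. The headers place all 4 arrays on 1 slide read in 1 scan, so neither slide nor scan could be fitted as a batch. No genome build is named in the sources used here, so no coordinates are given. Gene names and loci are those of the array design and can be old.

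Each array holds 45151 spots. Agilent controls (1417 spots) and oligos that stand for no gene (480 spots) were left out, leaving 42429 probes after spots of a probe were averaged. Mean signals were corrected with normexp (offset 50) against the median local background, normalised within each array by loess and tested with limma 3.58.1 in R 4.3.3 (an intercept, eBayes, two-sided, Benjamini-Hochberg adjustment over all tested probes). Spots that the scanner software marked as outliers were left out. A probe was tested where the same channel was well above background on at least 3 of 4 arrays, which left 34138 probes. A gene was represented by its brightest tested probe.

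The background step departs from the design fixed before the data were examined. As fixed, normexp used every local background as deposited. On array 4, where 4 spots had a local background above 30000, its fitted Cy5 background mean was -599, against 1.82 to 5.99 on the other arrays, and the SD of that array's log ratios was 0.41, against 0.59 to 0.75. The local background of spots that the scanner software had marked as background outliers was therefore replaced, on every array, by the median over the unmarked spots of that channel. The fitted mean on array 4 was then 8.87 and the SD 0.67. The choice was made after the counts with the step as fixed, and with no background correction, had been seen.

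The names follow a rule fixed before the data were examined: OsGLK1 and OsGLK2; the 15 highest and 12 lowest genes with adjusted p below 0.05, the same sign on all 4 arrays and a description that says what the product is (not hypothetical, unknown, uncharacterized, unnamed or a transposon, which leaves out retrotransposon genes); and, per gene list, up to 4 called members with the largest ratios. Descriptions reading unclassifiable or without a database hit were taken as not saying what the product is. The rule gave 82 genes, of which a part is printed. A gene not well above background in 1 channel on all arrays is given as a lower bound, from channel values after Aquantile normalisation. For the genes printed in this way the bound equals the fold change of the mean ratio. It therefore holds only for the reported normalisation, and another can give less. The 24 gene lists were matched by words in the descriptions; the list of plastid-encoded genes had no rows, since nothing in the files places a probe on the plastid chromosome. Lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with adjustment over 22 lists, and with fry. With a preset correlation, camera takes its degrees of freedom from the number of genes. With an estimated one it takes them from the 4 arrays, so small p-values are hard to reach whatever the correlation.

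The steps were tested on simulated intensities with 200 changed probes among 34140 tested. Of these changes, 58% of 2-fold, 86% of 4-fold and 92% of 8-fold ones were recovered, 12% of 1.5-fold ones, and 7 of 131 calls were false. The changed probes were drawn from brighter spots only, and noise did not depend on brightness. The rates therefore do not hold for dim probes. Of 200 simulated lists without a shift, 5 had a camera p below 0.05. These were lists of random probes with noise drawn independently for each spot. They do not show how often camera errs for genes that vary together, such as the photosystem list (estimated correlation 0.37). The alternatives fixed beforehand were no background correction, the deposited log ratios, the series values, median centring, scale normalisation between arrays, no filter and a stricter filter on dim probes, trend and robust moderation, separate channels, leaving out each array, leaving out saturated spots, an estimated correlation and the mean over a gene's probes. Backgrounds as deposited, backgrounds replaced on array 4 only and lists without accidental members were added after the data were seen.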

Results

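Callus of a rice line that overexpresses the full-length cDNA of OsGLK1, a GARP-family transcription factor known for its part in chloroplast development, was compared with callus of a vector control line. Both lines are of the cultivar Nipponbare, and callus is the unorganised tissue that seeds form on medium with auxin. The comparison asks which transcripts differ between the line that overexpresses OsGLK1 and the control line. A single line of each kind is described, so other differences between the lines cannot be told apart from the overexpression. The adjusted p-values do not measure spread between independent lines. Replicate pairs of RNA, 4 in all, were hybridised to 4 Agilent 2-colour rice arrays, with the control RNA in Cy3 and the OsGLK1-FOX RNA in Cy5 on every array. Ratios below are OsGLK1-FOX over vector control on the log2 scale, as the mean over the 4 arrays. Between 78.1% and 80.1% of the probes were well above background in Cy3, and between 80.0% and 81.6% in Cy5. No spot was saturated, and the number of arrays limits the precision. Because no dyes were swapped, a dye effect specific to a gene stays in its ratio.

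OsGLK1 (Os06g0348800) had the highest ratio of all named genes, 7.66 ± 0.18 (SD, n = 4; limma adjusted p = 3.01e-05), which is 203-fold. Its values on the arrays were 7.91, 7.63, 7.48 and 7.64. The array carries 6 probes for this gene. Of these, 5 were tested, with 3 different sequences among them, and all 5 were higher, by 6.70 to 7.66. The 3 sequences overlap and read a single stretch of the transcript, so they are not independent. The other probe was not well above background in either channel on any array. The 3 probes for OsGLK2 (Os01g0239000), the paralog of OsGLK1, were not well above background in either channel, so no ratio is given for it.

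The other genes among the 15 highest under the naming rule were photosynthesis or chlorophyll synthesis genes. This order holds for the reported normalisation: with the deposited log ratios a CONSTANS-like gene outside the 15, gene Os02g0731700, was at 7.14, above most of them. After OsGLK1 came plastocyanin (Os06g0101600), the copper protein that carries electrons to photosystem I, at 6.61 ± 0.34 (SD, n = 4; limma adjusted p = 3.32e-05). Chlorophyll a-b binding protein 2 (Os01g0600900) rose by 6.55 ± 0.56 (SD, n = 4), a glyceraldehyde-3-phosphate dehydrogenase (Os03g0129300) by 6.21 ± 0.44 and ferredoxin I (Os08g0104600) by 6.06 ± 0.35. CP12 (Os03g0306800), a small regulator of the Calvin cycle, rose by 5.49 ± 0.14. All of these were higher on 4 of 4 arrays, and every tested probe of each gene was called higher. Lowest among the genes under the naming rule, which leaves out transposon genes and transcripts of unknown product, stood S-adenosylmethionine synthetase 1 (Os01g0293000), at -3.90 ± 0.71 (SD, n = 4; limma adjusted p = 0.00182), an integrase domain gene (Os09g0491900) at -3.88 ± 1.34, and a pair of pepsin-type peptidases, Os10g0537800 at -3.38 ± 1.43 and Os10g0538200 at -2.75 ± 1.44.

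**Figure D1:**
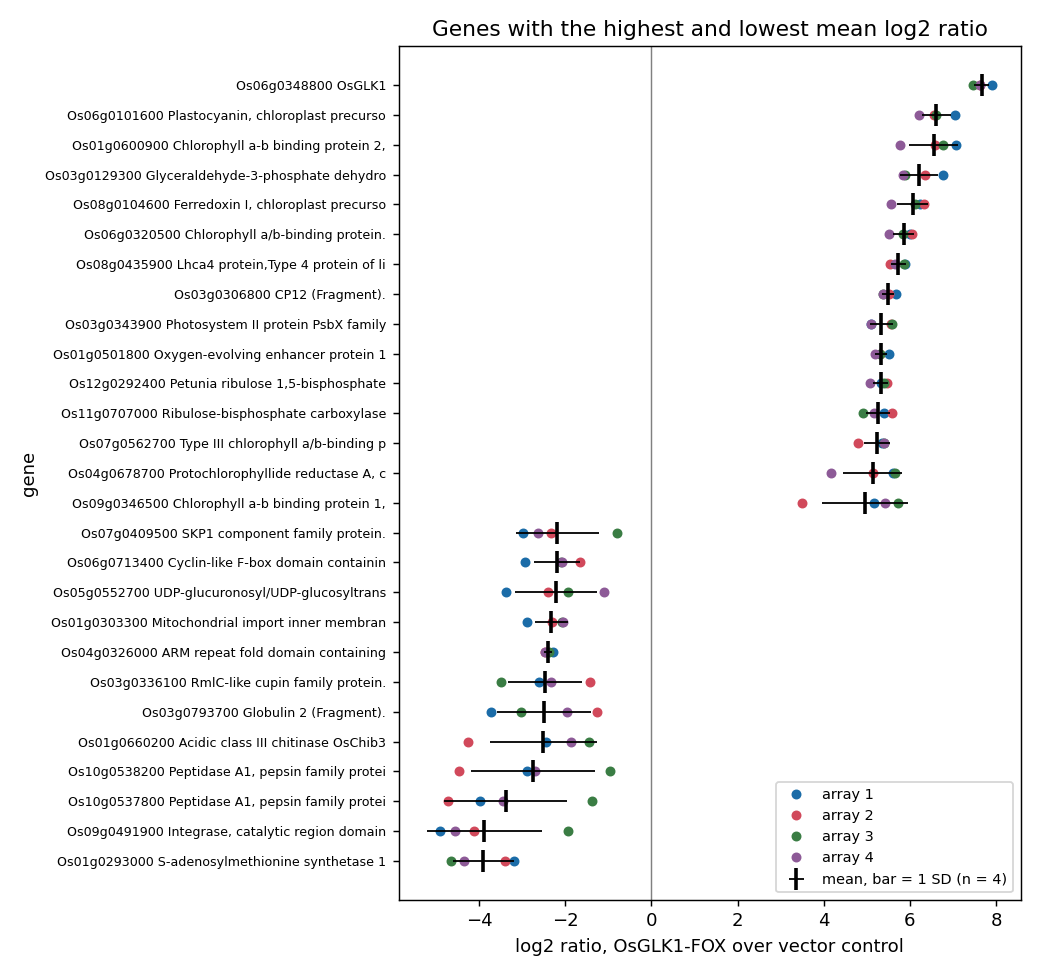
Log2 ratio of OsGLK1-FOX over vector control (horizontal axis) for the 15 highest and 12 lowest genes under the naming rule (vertical axis), with a coloured point for each of the 4 arrays and a black mark with a bar for the mean and 1 SD. OsGLK1 stands at 7.66 and S-adenosylmethionine synthetase 1 at -3.90, and most of the lower genes spread more between arrays than most of the higher ones.

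Of 34138 probes tested, 1878 were higher and 544 lower in OsGLK1-FOX callus (limma, adjusted p below 0.05), and 840 were higher and 181 lower by 2-fold or more. With 1 probe per gene, 1145 of 23498 loci were higher and 390 lower. These counts rest on a change to the background step that was made after the data were seen. With the step as it had been fixed beforehand, whose background model failed on array 4, 405 probes were higher and 34 lower, with 268 probes higher at least 2-fold and 16 probes lower at least 2-fold. With no background correction, an alternative fixed before the data were examined, 1868 were higher and 545 lower. The lower calls were the less secure: with variance moderation by trend and robust estimation, 722 probes were higher and 0 lower (limma; 4273 were lower at an unadjusted p below 0.05, against 4073 in the reported fit, and the smallest adjusted p of a lower probe was 0.123). Every call of a lower gene named in this text therefore ended with that moderation. Leaving out array 1, 2 or 4 gave 806, 905 and 820 probes higher in OsGLK1-FOX and 92, 133 and 88 probes lower in OsGLK1-FOX, while leaving out array 3 gave 1961 and 750. Probes lower at least 2-fold numbered 69, 67, 376 and 72 without arrays 1 to 4 in turn. Median centring in place of loess gave 7469 higher and 3470 lower, and separate channels 2830 and 1406. Of the calls, 77.5% were higher, against 66.8% with the deposited log ratios.

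The light-harvesting proteins, which bind chlorophyll and pass light energy to the photosystems, rose most as a group. Of 19 measured genes, 17 were higher, 0 lower and 2 did not pass (17 higher and 1 lower when adjusted over the list alone), with a median of 4.20. The gene lower in that count, named after its value was seen, is pseudo-response regulator 9 (Os03g0284100) at -0.26, a clock gene that its description placed in the list. Os06g0320500 rose by 5.85 ± 0.25 (SD, n = 4), Lhca4 (Os08g0435900) by 5.73 ± 0.17 and a type III chlorophyll a/b-binding protein (Os07g0562700) by 5.24 ± 0.30. The camera test gave an adjusted p of 4.19e-22 with a preset correlation, and an adjusted p = 0.164 with an estimated correlation. Here and for every list below, the latter form has few degrees of freedom, since it takes them from the 4 arrays. Its failure to pass is therefore not a measure of gene correlation alone. Of 31 photosystem and oxygen-evolving complex genes, 27 were higher and 0 lower (28 and 0 adjusted over the list alone), with a median of 3.31. PsbX (Os03g0343900) rose by 5.33 ± 0.27, oxygen-evolving enhancer protein 1 (Os01g0501800) by 5.32 ± 0.14 and photosystem I subunit IV (Os07g0435300) by 4.90 ± 0.37. Camera gave an adjusted p of 5.41e-31, and an adjusted p = 0.167 with an estimated correlation. The lists share 4 genes, Lhca4 among them.

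Photosynthetic electron carriers and Calvin cycle enzymes were also called higher as lists, with more members that did not pass. Of 17 electron transport genes 9 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.97. Leaf ferredoxin-NADP reductase (Os02g0103800), not well above background in the control on any array, was at least 12.3-fold higher (limma adjusted p = 0.000192). The members called also included oxygen-evolving enhancer protein 3-2 (Os07g0544800), a photosystem II protein, at 3.55 ± 0.36. Of 30 Calvin cycle genes 14 were higher and 0 lower (17 and 1 adjusted over the list alone), with a median of 0.56. They included a rubisco small subunit (Os12g0292400) at 5.32 ± 0.17 (SD, n = 4), rubisco activase (Os11g0707000) at 5.26 ± 0.28 and phosphoribulokinase (Os02g0698000), at least 15.8-fold higher. Camera gave an adjusted p of 2.12e-09 for both lists, and adjusted p = 0.164 and 0.142 with an estimated correlation. The Calvin cycle median was 1.22 without members whose descriptions matched by accident, a change made after the data were seen.

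Pigment synthesis rose in part. Of 19 chlorophyll synthesis genes 9 were higher and 0 lower (11 and 0 adjusted over the list alone; median 0.56). Protochlorophyllide reductase A (Os04g0678700), which makes chlorophyllide in the light, rose by 5.14 ± 0.68 (SD, n = 4), and magnesium chelatase family genes by 2.90 ± 0.28 (Os07g0656500) and 2.76 ± 0.28 (Os03g0323200). Of 12 carotenoid synthesis genes 3 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.32), lycopene epsilon-cyclase (Os01g0581300) at 1.80 ± 0.15, violaxanthin de-epoxidase (Os04g0379700) at 1.27 ± 0.21 and a phytoene dehydrogenase-related gene (Os03g0841900) at 0.58 ± 0.07. Camera gave adjusted p of 5.4e-08 and 0.00106, and an adjusted p = 0.206 for each list with an estimated correlation.

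Among genes for the plastid's own gene expression, the ribosomal protein list was called higher and the transcription list was not. Of 47 plastid-type ribosomal protein genes 17 were higher and 0 lower (24 and 2 adjusted over the list alone; median 0.32), with L28 (Os05g0101400) at 1.14 ± 0.14 (SD, n = 4); camera gave an adjusted p of 4.94e-08, and an adjusted p = 0.265 with an estimated correlation. Of 6 plastid transcription genes 3 were higher, all sigma factors, which direct the plastid RNA polymerase to promoters: SIG6 (Os08g0242800) rose by 2.98 ± 0.27, SIG5 (Os05g0586600) by 1.35 ± 0.55 and SIG2B (Os03g0271100) by 0.94 ± 0.09. Only 1 of 3 tested SIG5 probes was called. The other members, described as subunits of the plastid-encoded RNA polymerase, were at -0.09 (Os10g0355000), -0.45 (Os05g0293600) and -0.70 (Os04g0237300) and did not pass. Their probes may also read copies of plastid DNA in the nucleus, so these values need not be those of plastid transcripts. That list as a whole did not pass (camera adjusted p = 0.163; 3 higher and 1 lower adjusted over the list alone). Of 24 plastid import and division genes 2 were higher and 0 lower (2 and 2 adjusted over the list alone), Tic55 (Os02g0792800) at 1.67 ± 0.43 and Tic32 (Os09g0570300) at 0.80 ± 0.13, and the list's median was -0.04 (0.099 with median centring), with a mean of 0.05 and camera direction down (adjusted p = 0.802). The calls for SIG5, Tic32 and the phytoene dehydrogenase-related gene ended with trend and robust moderation.

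Of 23 light response and clock genes 8 were higher and 0 lower (12 and 1 adjusted over the list alone; median 0.52). They were led by CONSTANS-like genes, zinc-finger regulators, with Os02g0731700 at 4.66 ± 0.16 (SD, n = 4), where 1 of 2 tested probes was called, and Os03g0711100 at 3.15 ± 0.40. In the control, each of these was well above background on 1 of 4 arrays, so the size of their ratios is uncertain, and the deposited log ratios gave 7.14 for gene Os02g0731700 and 5.97 for gene Os03g0711100. An early light-inducible protein (Os07g0178700) rose by 1.69 ± 0.40. Camera gave an adjusted p of 1.97e-05, and an adjusted p = 0.265 with an estimated correlation, and the median was 0.83 without array 3. Of 24 photorespiration genes 7 were higher and 0 lower, the same adjusted over the list alone, among them glycolate oxidase (Os03g0786100) at 2.05 ± 0.56 and hydroxypyruvate reductase (Os02g0101500) at 1.98 ± 0.32, but the median was 0.02 and the list did not pass (camera adjusted p = 0.105), although it did without array 3 and with median centring.

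Some of the seed and embryo genes were lower. Of 30 measured, 0 were higher, 9 lower and 21 did not pass (2 and 18 adjusted over the list alone), with a median of -1.16 and medians of -2.09, -0.86, -0.85 and -0.48 on the 4 arrays. Globulin 2 (Os03g0793700), a storage protein, was at -2.50 ± 1.10 (SD, n = 4), an oleosin of the oil-body surface (Os04g0546500) at -2.12 ± 1.04 and late embryogenesis abundant proteins at -2.09 ± 1.04 (Os08g0327700) and -2.07 ± 0.94 (Os02g0250600). Camera gave an adjusted p of 9.61e-07, and an adjusted p = 0.265 with an estimated correlation. The median was -0.72 without array 1 and -0.10 with dim probes kept, and none of the genes named here was called lower by the trend and robust moderation.

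**Figure D2:**
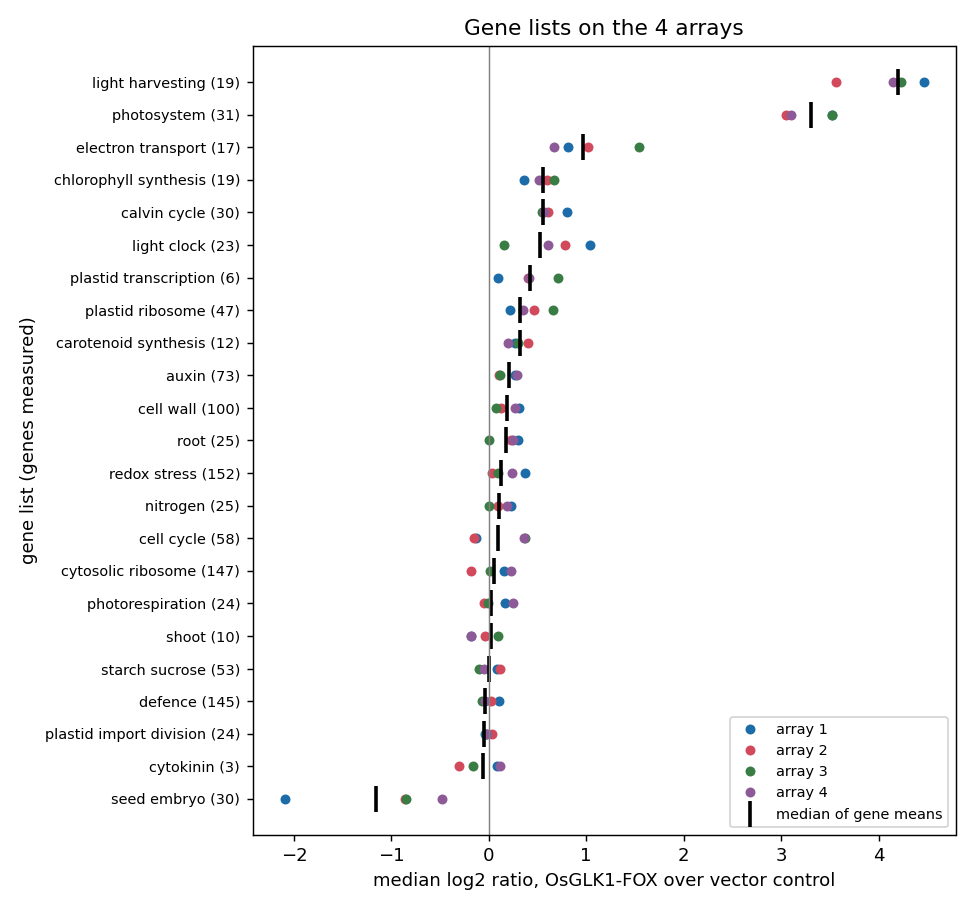
Median log2 ratio of OsGLK1-FOX over vector control (horizontal axis) of each of the 23 gene lists with measured genes (vertical axis, genes measured in brackets), with a coloured point for each of the 4 arrays and a black mark for the median of the gene means. The light harvesting list stands highest at 4.20 and the seed and embryo list lowest at -1.16.

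The cell wall, redox, auxin and root lists were also called higher by camera. In the cell wall list 9 of 100 genes were higher and 1 lower (21 and 3 adjusted over the list alone; median 0.19; camera adjusted p = 0.00249, and adjusted p = 0.213 with an estimated correlation), with a beta-expansin (Os03g0102700) at 2.86 ± 0.39 (SD, n = 4). In the redox list 12 of 152 were higher and 4 lower (19 and 7 adjusted over the list alone; median 0.13; camera adjusted p = 0.00802, and adjusted p = 0.442 with an estimated correlation), with thylakoid-bound ascorbate peroxidase (Os02g0553200) at 1.79 ± 0.38 and peroxiredoxin 6 (Os07g0638300) at -1.61 ± 0.50. In the auxin list 2 of 73 were higher and 0 lower (0 and 0 adjusted over the list alone; median 0.21; camera adjusted p = 0.00552, and adjusted p = 0.265 with an estimated correlation), a SAUR gene (Os08g0118500) at 0.77 ± 0.31 and an Aux/IAA gene (Os01g0231000) at 0.45 ± 0.14, both of whose calls ended with trend and robust moderation (gene Os01g0231000 was at 0.85 with median centring). In the root list 3 of 25 were higher and 2 lower (7 and 3 adjusted over the list alone, median 0.18). Camera gave an adjusted p of 0.0399, and an adjusted p = 0.371 with an estimated correlation. The root-specific protein RCc2 (Os04g0612500) was at 2.20 ± 0.86. The lower genes were Scarecrow-like genes, GRAS-family regulators, with Scarecrow-like 9 (Os11g0705800) at -1.23 ± 0.52. They were matched by the word scarecrow and need not mark root. Without members matched by accident, a change made after the data were seen, the root median was 0.77. The auxin, redox, cell wall and root calls ended with median centring, although the medians were then higher (0.29, 0.29, 0.31 and 0.53), as was the median of all probes (0.15 against 0.01). The redox call also ended without array 1 (median 0.097), and the root call without array 2 or array 4 (median 0.18 in both). The redox median was 0.20 without array 2, and the cell wall median 0.12 without array 1.

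No camera call was made for the other lists. In the defence list 4 of 145 were higher and 5 lower (2 and 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.339). PR-1 (Os07g0125000) rose by 3.26 ± 0.18 (SD, n = 4) and a class III chitinase (Os01g0660200) was at -2.51 ± 1.24. The list also holds genes described only by a pathogenesis-related factor and ERF domain, which need not act in defence. Os05g0437100, called lower at -1.20 ± 0.56, is among them. With median centring that list's median was 0.020, below that of all probes, and camera called it lower; leaving out 1 array gave medians of -0.07 to 0.02, with a change of sign and no call. In starch and sucrose metabolism 3 of 53 were higher and 3 lower (6 and 5 adjusted over the list alone; median 0.01, -0.07 to 0.03 with 1 array left out and 0.12 with median centring; mean -0.10, camera direction down; adjusted p = 0.853), with a starch synthase (Os02g0744700) at 1.11 ± 0.03 and an alpha-amylase (Os02g0765300) at -1.38 ± 0.52. In nitrate assimilation 1 of 25 was higher (1 adjusted over the list alone; median 0.11; camera adjusted p = 0.163), the chloroplast glutamine synthetase (Os04g0659100) at 1.10 ± 0.34, a call that ended with trend and robust moderation. With median centring this list's median was 0.34 and it was called higher, and leaving out 1 array gave medians of 0.05 to 0.13 without a call. Of 147 cytosolic ribosomal protein genes and 58 cell cycle genes, 1 each was higher (1 each adjusted over the list alone), with medians of 0.05 and 0.10 (camera adjusted p = 0.157 and 0.0943). They were ribosomal protein L38 (Os05g0507200) at 1.17 ± 0.19 and a cyclin-dependent kinase (Os05g0480000), at least 1.75-fold higher, whose call ended with trend and robust moderation. The deposited log ratios gave 2.25 for gene Os05g0507200, and median centring gave 0.37 for gene Os05g0480000, less than that bound. With median centring these medians were 0.51 and 0.42 and both lists passed, as the cell cycle list did without array 1 or 2 (0.21 and 0.20) and the ribosome list without array 2 (0.12). Of 10 shoot markers limma called 0 (0 adjusted over the list alone; 2 higher and 1 lower at an unadjusted p below 0.05), with a median of 0.02 (-0.13 to 0.09 with 1 array left out, and -0.31 with median centring), a mean of -0.08 and a camera adjusted p of 0.973. The cytokinin list had 3 measured genes, too few to test, with 0 called by limma (0 at an unadjusted p below 0.05) and a median of -0.06. By fry, which tests whether the genes of a list move one way on balance, the lists of seed and embryo, plastid transcription and photorespiration genes passed (adjusted p = 0.0333, 0.0117 and 0.0168), as did every list called by camera except redox and root (adjusted p = 0.101 and 0.0559).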

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

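The tests on the photosynthesis and embryo genes in this part were chosen after those results were seen; the tests on differences between arrays were fixed before.

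Among 105 values tested for an array far from the others, 3 stood out, and chance would give about 5.25. Os07g0562700, a type III chlorophyll a/b-binding protein, was at 4.79 on array 2 and between 5.35 and 5.40 on the others. Tic32 (Os09g0570300) was at 0.61 on array 3 and between 0.85 and 0.89 on the others. A phytoene dehydrogenase-related gene (Os03g0841900) was at 0.47 on array 4 and between 0.60 and 0.62 on the others. Of 480 oligos that stand for no gene, which the comparison does not use, 45 were well above background on every array, 31 of 240 genomic and 14 of 120 random ones, against 0 of 120 artificial ones.

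Most light-harvesting and photosystem genes were called higher (17 of 19 and 27 of 31), with a median of 3.64 over the 46 genes of both lists. That median lay above that of 100% of 10000 random gene sets matched on probe base composition and brightness, whose highest was 0.18. The probes of these 46 genes had a median G and C content of 40%, and those of all genes 40%. The matched sets were thus of ordinary base composition, and low medians were to be looked for in them. The ordinary base composition of the 46 genes itself argues against a dye effect that follows it. For brightness the outcome was fixed in advance, since loess had already centred the ratios along brightness, so no conclusion is drawn there. Shoot or leaf primordia in the OsGLK1-FOX callus cannot be told apart from a change within callus cells, since the shoot markers had a median of 0.021 with members on both sides (SD 0.72), and leaving out 1 array gave -0.13 to 0.089. Dye effects specific to single genes are also present in the matched sets, so they are argued against as the whole of the rise, while the size of each gene's ratio stays open to them. The overexpression of OsGLK1 that the design names also stays open, untested beyond the comparison itself, as do other differences between the lines.

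The genes of the seed list called lower after adjustment over all probes were all embryo genes (globulins, oleosins and late embryogenesis abundant proteins). The embryo genes had a median of -1.40 over 24 genes, 9 of them called. Adjusted over the list alone, the lower genes also took in the endosperm glutelins Os01g0607000 at -0.40 and Os10g0400200 at -0.23. For leftover endosperm in the control callus, 6 endosperm storage genes had a median of -0.18 (SD 0.31), above the -0.70 that would be needed. This argues only against endosperm that carries these storage transcripts, and leftover endosperm without them stays open. The genes were grouped after the values were seen. They were dimmer in the control than the embryo genes, with a mean log2 Cy3 signal of 9.66 against 12.40. Array 1 alone does not account for the lower embryo genes: without it their median was -1.08, and their medians on the other arrays were -1.03, -1.13 and -0.78. Leftover embryo tissue, slower loss of the embryo programme in the control, other differences between the lines and the overexpression itself stay open and were not tested.

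The arrays differed in how alike their log ratios were across probes, with r from 0.57 to 0.86 between pairs of arrays (probes are not independent replicates). Spot noise or spot position is argued against: over 5416 genes with a pair of probes of different sequence, the pair's deviations from their own means correlated at 0.83 or more on each array. A trend with probe brightness and base composition explained at most 1.13% of the variance of an array's deviations. For brightness a small share was largely fixed in advance, since loess had already centred each array's ratios along it, so no conclusion is drawn there. Differences between the RNA samples, from culture, extraction or labelling, stay open, and no biological explanation was tested.

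Reversing the sign of arrays gives 8 splits, too few for a share under 0.05. The reported split gave 1878 higher and 544 lower probes, 840 and 181 by 2-fold or more, and the highest count of any other split was 0; 1 of the 8 splits, the reported one, gave a count as large in each case.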

How the results depend on the processing

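The added alternatives here, deposited backgrounds, backgrounds replaced on array 4 only and lists without accidental members, were chosen after the data were seen; the others were fixed before the data were examined. The OsGLK1 log2 ratio stayed past the threshold under every setting run, between 7.12 and 8.46. The counts that follow are of probes higher in OsGLK1-FOX, probes lower in OsGLK1-FOX, probes higher at least 2-fold and probes lower at least 2-fold. With deposited backgrounds, 405 probes were higher and 34 lower (268 and 16 by 2-fold or more); all 405 and 33 of the 34 were also called in the reported fit, and replacing the backgrounds on array 4 only gave 1867 and 546 (836 and 179 by 2-fold or more), 1866 and 541 of them also called in the reported fit. For the other changes below the cause was not tested. Median centring gave 7469 higher and 3470 lower (1316 and 376 by 2-fold or more) and a median of all probes of 0.15 against 0.01. Trend and robust moderation gave 722 higher and 0 lower, with 0 lower by 2-fold or more; separate channels gave 2830, 1406 and 283. The deposited log ratios and the series values gave 304 and 306 probes lower by 2-fold or more, and 66.8% of calls higher with the former. Leaving out each array gave 806 to 1961 higher, 88 to 750 lower and 67 to 376 lower by 2-fold or more. With median centring the lists that gained a camera call were photorespiration (0.28), nitrogen (0.34), cytosolic ribosome (0.51), cell cycle (0.42) and defence (0.020, a median of changed sign but a call lower), and those that lost it, at higher medians, were auxin (0.29), redox (0.29), cell wall (0.31) and root (0.53). The deposited log ratios and the series values each added cytosolic ribosome (0.032) and cell cycle (0.074 and 0.075). Separate channels ended the root call (0.18). Leaving out an array moved a call for cell cycle (medians 0.0078 to 0.21), cytosolic ribosome (-0.00069 to 0.12), photorespiration (-0.0071 to 0.13), redox (0.097 to 0.20) and root (0.13 to 0.24). With an estimated correlation no list passed, at medians of 4.20 (light harvesting), 3.31 (photosystem), 0.97 (electron transport), 0.56 (Calvin cycle), 0.56 (chlorophyll), 0.32 (carotenoid), 0.32 (plastid ribosome), 0.52 (light and clock), 0.21 (auxin), 0.13 (redox), 0.19 (cell wall), -1.16 (seed and embryo) and 0.18 (root). A larger correlation does not account for every lost call. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays instead of the number of genes. Calls can therefore be lost at an equal or smaller correlation. The estimate for the Calvin cycle list was 0.003, below the preset 0.01, and for the photosystem list 0.37. Of 81 named genes other than OsGLK1, 33 lost their call with trend and robust moderation, 50 with deposited backgrounds and 23, 26, 9 and 25 without arrays 1 to 4; none changed sign past the threshold under any setting run. No spot was saturated, so leaving saturated spots out changes nothing and shows nothing, and slide or scan as a block was not run, since there was 1 of each. Signal over background limits the dim genes, whose ratios are compressed.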

Other observations

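The tests and the genes named in this part were all chosen after the values were seen.

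Some words of the gene descriptions were more frequent among higher genes than among all 23498 tested (one-sided Fisher's exact test, 577 words, Benjamini-Hochberg adjustment). Some of these genes are also members of the lists described so far. Rhodanese-like proteins, which carry a sulphur-transfer domain, were higher at 9 of 16 loci and lower at 1 (adjusted p = 1.04e-06). Proteins described with the word thylakoid were higher at 8 of 11 loci (adjusted p = 4.32e-07). Peptidyl-prolyl isomerases, which help proteins fold, were higher at 6 of 24 loci and lower at 1 (adjusted p = 0.0344). Genes described with the word thioredoxin, a thioredoxin peroxidase (Os02g0192700) among them, were higher at 6 of 25 loci (adjusted p = 0.0405). Cytochrome P450 genes went both ways, with 16 of 158 higher and 8 lower (adjusted p = 0.0973 for higher and 0.288 for lower).

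Loci of the array design whose products plastid genomes encode were split. Of 13 loci for photosynthesis products 8 were higher, with a median of 0.86: photosystem II protein D1 (Os04g0236400) was at 3.31 ± 0.18 (SD, n = 4) and a rubisco large chain (Os06g0598500) at 3.05 ± 0.43. The 3 loci for subunits of the plastid-encoded RNA polymerase had a median of -0.45 and none was called. The difference of the medians was 1.25 ± 0.50 (SD, n = 4) and above 0 on 4 of 4 arrays. That photosynthesis genes of the plastid genome rise while its RNA polymerase genes do not is a hypothesis drawn from these same loci, which cannot test it. The probes may also read copies of plastid DNA in the nucleus.

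Genes at least 2-fold lower lay next to each other along the locus order more often than random genes: 7 neighbouring pairs among 144 genes, against a median of 1 and a highest of 7 in 10000 random sets. Genes at least 2-fold higher did so too, with 28 pairs among 473 genes against a random median of 9. The lower pairs included a transcript without coding sequence (Os05g0263300 at -4.03) beside a retrotransposon gag gene (Os05g0263200), and pairs with like descriptions such as the peptidases Os10g0537800 and Os10g0538200. Whether lower genes cluster along the chromosomes stays open, since the count of 7 was made after the values were seen and probes that read near-identical neighbours may add to it.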
